A study of Mus musculus with 24 samples.

How the data were processed

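RNA from mouse hearts was sequenced 3 weeks after myocardial infarction. All mice had been ovariectomised and had received an adeno-associated virus, AAV9, that was either empty or carried miR-21, and part of them had trained by swimming before the infarction. Per the labels, RNA was extracted with TRIzol and libraries were made with a stranded poly(A) mRNA kit. Per the deposited processing notes the genome build was GRCm39. The aligner and the program that counted reads are not given in the sources used here.

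Per the labels and the values, the authors' table holds a raw count for each gene and library: whole numbers that were not normalised. The authors also deposited 4 comparison tables, whose log2 values are the log2 of the mean normalised count of 1 group over that of another. The p-value and adjusted p-value columns of those tables were computed by the authors, with a tool that is not named in them. The counts were used for every test here, and the 4 tables only for a comparison with the authors' own calls. FPKM values of the same libraries were not used, and nor were 69 other per-sample columns of the analysed samples. All 23 count columns matched a sample title. Replicate 6 of the miR-21 swimming group was not analysed here. No coordinates are printed, since the annotation at hand is of an earlier build than the counts. It was used only for 3' untranslated region (UTR) sequences, gene lengths and which genes lie next to each other.

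Libraries held 12744241 to 14657630 counts. Groups came from the sample labels: 6 libraries with the empty vector without swimming, 6 with the empty vector and swimming, 6 with the miR-21 vector without swimming, and 5 with the miR-21 vector and swimming. Nothing in the labels says that each library came from a separate mouse, so p-values measure the spread between samples. The 4 comparisons of groups and the difference between the effects of swimming under each vector (the interaction) were tested.

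Genes were filtered with filterByExpr, which left 13501, and normalised by trimmed mean of M-values (TMM). All 23 libraries entered 1 edgeR quasi-likelihood model with robust dispersion, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Errors of log2 fold changes are standard errors (SE) from that model, and CPM values, counts scaled to library size, are TMM-normalised and given with the standard deviation (SD). The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

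Gene lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined. Of 733 distinct genes in 34 lists of cell types, pathways and processes, 723 were in the count table and 681 of the listed genes were tested. Each list was tested against all other genes with camera at a preset correlation of 0.01, and again with the correlation between genes estimated from the libraries. A list score per library is the mean of the list's log2 CPM, with a prior count of 2, after centring each gene. Scores of 2 groups were compared by a two-sided exact permutation test of the difference in means over all splits, 924 for 6 libraries against 6. Gene Ontology and KEGG terms of 15 to 300 tested genes were tested in the same way. In each comparison the genes named are Vmp1 and Sox7 always, the 10 largest rises and 10 largest falls among changed genes with a symbol other than a Gm number or a Rik name, a mean of at least 1 CPM and the change in at least 5 libraries, and from each list up to 4 changed genes with the smallest p, or up to 2 as values where none changed. Libraries that moved in a direction are those on that side of the other group's mean log2 CPM. The condition of 5 libraries was not applied to the interaction. The naming rule also named the miR-21 precursor gene, for which the table has 0 rows. Genes outside the rule are marked as chosen after their values were seen.

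Sites for miR-21 were searched in the 3' UTRs of 13290 tested genes, with UTRs of at least 30 bases. The difference in mean log2 fold change between genes with and without the 7-base site was ranked against that for all other 7-base words found in a number of genes within 10 percent of that of the site. The two-sided p is the share of those words with a difference as far from their median.

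The alternatives fixed beforehand were other scaling factors (RLE, upper quartile), no filter or a stricter one (a mean of at least 1 CPM), DESeq2, limma voom with quality weights, a fold minimum of 1.5, only the 2 groups compared, a term for the number series of the sample titles, leaving out each of the 23 libraries, an estimated correlation, and lists without shared members. Alternatives added after seeing the data were leaving out the 3 libraries with the highest adipocyte scores, and the adipocyte and mesothelial scores as covariates. Each count of changed genes was compared with that of 100 splits of the same libraries, the real one included. Chance in comparisons that share a group was measured with 20 simulations of unchanged groups, each gene drawn independently, and 20 splits of the shared group into equal parts. The methods were tested on simulated data with 200 changed genes. With edgeR, the share of genes with a planted 1.5-fold change that was recovered was 55.2% for swimming with the empty vector (13431 genes), 56.7% for the miR-21 vector without swimming (13425 genes), 62.7% for the miR-21 vector with swimming (13422 genes), 58.2% for swimming with the miR-21 vector (13429 genes) and 38.8% for the interaction (13426 genes).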

Results

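Gene expression was measured by RNA sequencing in hearts of ovariectomised mice 3 weeks after myocardial infarction. The mice had received AAV9, a virus used to carry genes to the heart, that was empty or overexpressed the microRNA miR-21, and had or had not trained by swimming before the infarction. There were 6 libraries with the empty vector without swimming (13442909 to 14657630 counts), 6 with the empty vector and swimming (13343385 to 14082098), 6 with the miR-21 vector without swimming (12744241 to 14608507) and 5 with the miR-21 vector and swimming (12839383 to 14546209). The numbers in the sample titles form 1 series in both groups without swimming and a separate, higher series in the empty vector swimming group. The miR-21 swimming group has both, the lower series for replicates 1 and 2 and the higher for replicates 3 to 5. Pearson correlations of log2 CPM between replicates ran from 0.912 to 0.990 across genes, the lowest in the miR-21 swimming group, and 0 of all 253 pairs of libraries had identical counts.

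The first principal component took 43.9% of the variance and set apart 3 libraries: replicate 2 of the miR-21 swimming group (84.3) and replicates 2 and 5 of the empty vector control (64.6 and 57.2). The same 3 libraries had the highest scores of the adipocyte list, at 2.41, 2.68 and 2.53 log2 units against at most 0.69 in the other 20. The second component took 12.6% and held all 6 empty vector swimming libraries at 19.8 or above.

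Changed genes numbered 1007 for swimming with the empty vector, 304 for the miR-21 vector without swimming, 618 for the miR-21 vector with swimming and 23 for swimming with the miR-21 vector, of 13501 tested. The effect of swimming differed between the vectors in 73 genes. At an unadjusted p under 0.05 the numbers were 3148, 3828, 2678, 2532 and 2899.

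**Figure D1:**
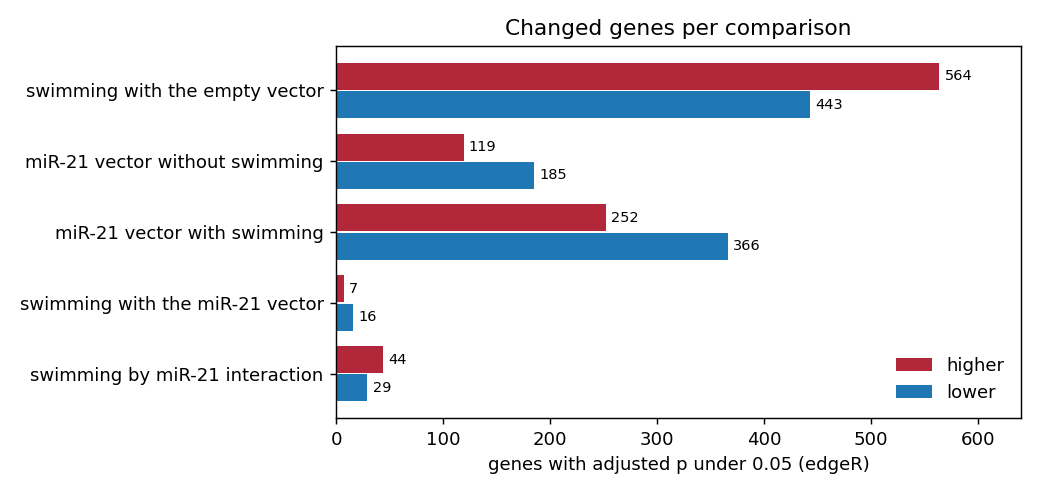
Number of genes with an edgeR adjusted p under 0.05 that were higher or lower in each comparison, with bars starting at 0. Swimming changed 564 genes upwards and 443 downwards with the empty vector, and 7 and 16 with the miR-21 vector.

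The title of the series names Sox7, a transcription factor of endothelial cells, together with miR-21. Sox7 stood at 33.3 ± 8.94 CPM (SD, n = 6) in the empty vector control, 49.3 ± 10.7 (n = 6) with swimming, 32.4 ± 5.49 (n = 6) with miR-21 and 27.5 ± 6.87 (n = 5) with miR-21 and swimming. In swimming mice it fell with the miR-21 vector, with a log2 fold change of -0.84 ± 0.19 (SE, edgeR adjusted p = 0.0144), and was lower in 5 of 5 libraries. The alternatives run for single genes numbered 28: DESeq2, RLE scaling, the title number series, each of 23 libraries left out, and the 2 chosen after seeing the data. This call held under 28 of 28, with values from -0.95 to -0.72 and adjusted p from 0.000798 to 0.0415. With the empty vector, swimming gave a Sox7 log2 fold change of 0.57 ± 0.18 (adjusted p = 0.0546, higher in 6 of 6 libraries), and 5 of 28 alternatives passed. Without swimming the miR-21 vector gave -0.04 ± 0.18 (adjusted p = 0.907), and swimming with the miR-21 vector gave -0.24 ± 0.19 (adjusted p = 0.486). The interaction for Sox7 was -0.81 ± 0.26 (adjusted p = 0.103), so a difference between the arms did not pass.

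Vmp1, a membrane protein of autophagy whose gene overlaps that of miR-21, stood at 61.8 ± 13.5, 45.6 ± 3.20, 53.7 ± 5.22 and 49.4 ± 11.2 CPM (SD, n = 6, 6, 6 and 5) in the same order. Vmp1 fell with swimming under the empty vector, at -0.44 ± 0.12 (SE, edgeR adjusted p = 0.0309, lower in 6 of 6 libraries). The call held under 20 of the same 28 alternatives, and the value was -0.11 (adjusted p = 0.696) with a term for the title number series. That term is set by miR-21 swimming replicates 3 to 5 against 1 and 2. Replicate 2 had 68.4 CPM of Vmp1 and replicate 1 had 39.1. The miR-21 vector gave -0.20 ± 0.12 (adjusted p = 0.262) without swimming and 0.12 ± 0.13 (adjusted p = 0.66) with it, swimming with the miR-21 vector gave -0.12 ± 0.13 (adjusted p = 0.614), and the interaction was 0.32 ± 0.18 (adjusted p = 0.293). The count table has 0 rows for the miR-21 precursor gene, so expression from the vector was not measured.

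**Figure D2:**
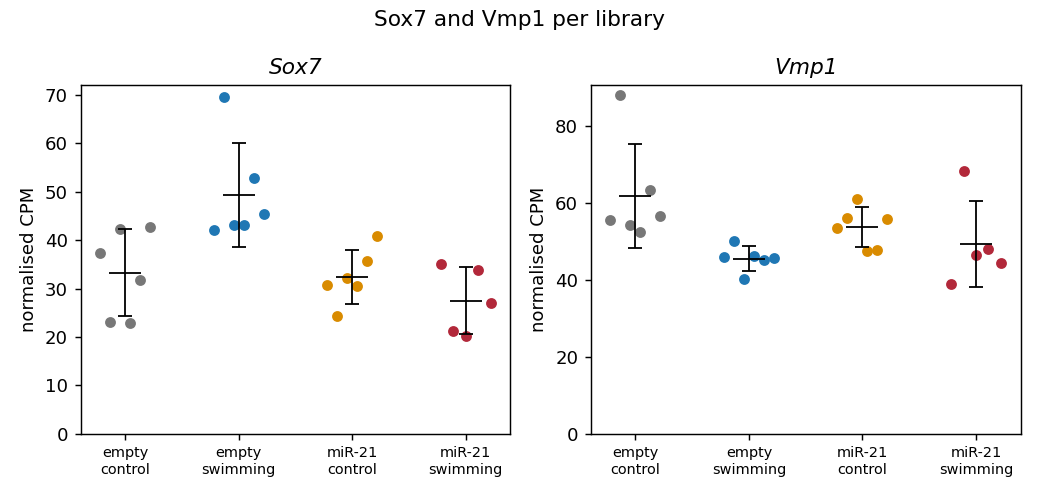
Normalised CPM of Sox7 and Vmp1 in each library (points) of the 4 groups, with the mean and SD as bars; both axes start at 0. Sox7 averaged 49.3 CPM in the empty vector swimming group and 27.5 in the miR-21 swimming group.

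Swimming with the empty vector was compared with no swimming to ask what training before the infarction changed in the heart. Genes of cell division rose: Ttk, a kinase of the spindle checkpoint, by a log2 fold change of 2.28 ± 0.49 (SE, n = 6 and 6, adjusted p = 0.00707), Ect2, which drives cytokinesis, by 2.12 ± 0.40 (0.00282), and Neil3, Fam64a, Kif18b, Melk, Mxd3 and Casc5 by 2.01 to 2.27. Larger still were the rises of Pydc3 at 3.91 ± 0.49 (6.36e-05) and Wif1, a secreted Wnt inhibitor, at 2.51 ± 0.33 (0.00012). The largest falls were in genes of fat and of the mesothelium that lines the heart: Upk3b -6.24 ± 1.79 (0.0383), Cidec -6.03 ± 1.59 (0.0262), Cfd -5.98 ± 1.54 (0.024), Adipoq -5.54 ± 1.38 (0.0196) and Car3 -5.45 ± 1.41 (0.0244), with Hp, Chil1, Nfasc, Cyp2e1 and Ccl19 between -5.70 and -4.32. Each of these moved in its direction in 6 of 6 swimming libraries, where the naming rule required at least 5. The size of the falls in fat genes rests on empty vector control replicates 2 and 5, with 148 and 114 CPM of Cfd against at most 8.47 in the other controls. Without the 3 adipocyte-high libraries Cfd was -2.75 (adjusted p = 0.0129) and Upk3b -6.07 (0.00853). With the adipocyte and mesothelial scores as covariates Cidec was 0.27 (0.863), Car3 0.057 (0.927) and Upk3b -3.17 (0.00283). Both alternatives were chosen after seeing the data. Cidec lost its call without control replicate 2 (-5.23, 0.051) or 5 (-5.50, 0.0554), Upk3b without 2 (-6.28, 0.0509) or 5 (-6.07, 0.068), and Car3 without 5 (-4.94, 0.0513).

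The cell cycle list rose, with 13 of 26 genes up, 23 adjusted over the list alone, and a median log2 fold change of 1.26 (camera adjusted p = 3.04e-12, adjusted p = 0.449 with an estimated correlation). Nusap1 (1.72), Ccna2 (1.71), Cenpf (1.32) and Pcna (0.31) were among them. The endothelial list rose by a median of 0.15, with 7 of 27 genes up, 8 adjusted over the list alone (camera adjusted p = 0.000255, adjusted p = 0.449 with an estimated correlation). Erg (0.48 ± 0.09), the adhesion genes Icam2 (0.58 ± 0.12) and Cdh5 (0.44 ± 0.09), and Rasip1 (0.31 ± 0.07) rose. In the pericyte and smooth muscle list 5 of 16 genes rose, and 5 adjusted over the list alone, with Rgs5 at 0.56 and Smtn at 0.57 (camera adjusted p = 0.0128, adjusted p = 0.449 with an estimated correlation). The activated fibroblast list fell by a median of -0.75, with 7 of 29 genes down, 10 adjusted over the list alone (camera adjusted p = 4.32e-08, adjusted p = 0.451 with an estimated correlation). Comp (-4.16 ± 0.89) and Chad (-4.12 ± 0.93) of cartilage-like matrix, the secreted protein gene Wisp2 (-2.75 ± 0.57) and the protease inhibitor gene Timp1 (-2.41 ± 0.59) fell. Exact permutation tests of the scores gave p = 0.00216 for the cell cycle, 0.0108 for the endothelial, 0.00649 for the pericyte and 0.0173 for the activated fibroblast list, adjusted over 34 lists 0.0245, 0.0335, 0.0294 and 0.0421.

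Genes of glycolysis and hypoxia fell, 7 of 26 and 9 adjusted over the list alone, among them the collagen hydroxylase P4ha1 at -0.91 ± 0.12 (adjusted p = 9.72e-05) and Bnip3 at -0.56 ± 0.10 (camera adjusted p = 0.00109 for the list, adjusted p = 0.451 with an estimated correlation). In the TGF-beta list Bmp2 (-1.66 ± 0.29), Tgfb2 (-1.10) and Inhbb (-0.97) fell and Ltbp1 (0.44) rose (camera adjusted p = 0.000369, adjusted p = 0.449 with an estimated correlation). In the Wnt list Wnt2 (-1.66) and Sfrp4 (-3.31) fell, and Wif1 and the cyclin gene Ccnd1 (0.66 ± 0.12) rose (camera adjusted p = 0.00457, adjusted p = 0.451 with an estimated correlation). The other lists called downwards by camera had these medians: cardiac stress -0.83, fibrillar collagen and matrix -0.68, macrophage -0.91, neutrophil -2.23, T and NK cell -1.08, B cell -1.39, adipocyte -2.79, mesothelial -1.85, inflammatory cytokines -0.75 and immediate early genes -0.29. Those called upwards were fatty acid oxidation (0.16), oxidative phosphorylation (0.16), interferon response (0.15) and ion channels (0.14). With an estimated correlation these 14 lists had adjusted p from 0.449 to 0.561, and 0 of the 34 lists passed. With the title number series and with the tissue covariates the camera direction turned for matrix (means 0.44 and 0.14), macrophage (0.55 and 0.49), neutrophil (1.10 and 1.11), B cell (1.57 and 0.75), mesothelial (0.79 and -0.50) and inflammatory cytokines (0.042 and 0.28). It also turned for fatty acid oxidation (-0.30 and -0.14), oxidative phosphorylation (-0.20 and -0.18) and ion channels (-0.10 and -0.083). Wnt turned with the title series alone (0.16) and T and NK cell with the covariates alone (0.45). The title series term is set by miR-21 swimming replicates 3 to 5 against 1 and 2. Replicate 2 is adipocyte-high, so turns with this term carry its tissue and cannot be read as the removal of a batch. Osteopontin, Spp1, fell by -4.19 ± 0.96 in the macrophage list, and the growth arrest gene Cdkn1a fell by -1.36 ± 0.22 (0.00133).

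The 13 lists not called had these medians: miR-21 literature targets 0.06, cardiomyocyte sarcomere 0.06, resting fibroblast -0.09, atrial and conduction tissue -0.17, nerve 0.40, skeletal muscle -0.46, erythrocyte -0.29, SoxF partners 0.07, exercise-linked genes -0.02, heat shock -0.08, circadian clock 0.22, oestrogen-linked genes -0.18, and apoptosis and p53 -0.11. The miR-21 targets had a negative mean, -0.02, beside a positive median and test. Within the clock list 5 genes rose and 2 fell, with Wee1 at 0.94 ± 0.13 (0.00012) and Hlf at 0.70 ± 0.16. A term for the title number series, which only the miR-21 swimming group can separate from swimming, gave 164 changed genes, 110 of them among the 1007. With it 73 of the 90 named changed genes lost their call. The count of 1007 became 654 and 620 without empty vector control replicates 4 and 5, 629, 645 and 607 without empty vector swimming replicates 1, 2 and 5, and 1922 without miR-21 swimming replicate 2.

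**Figure D3:**
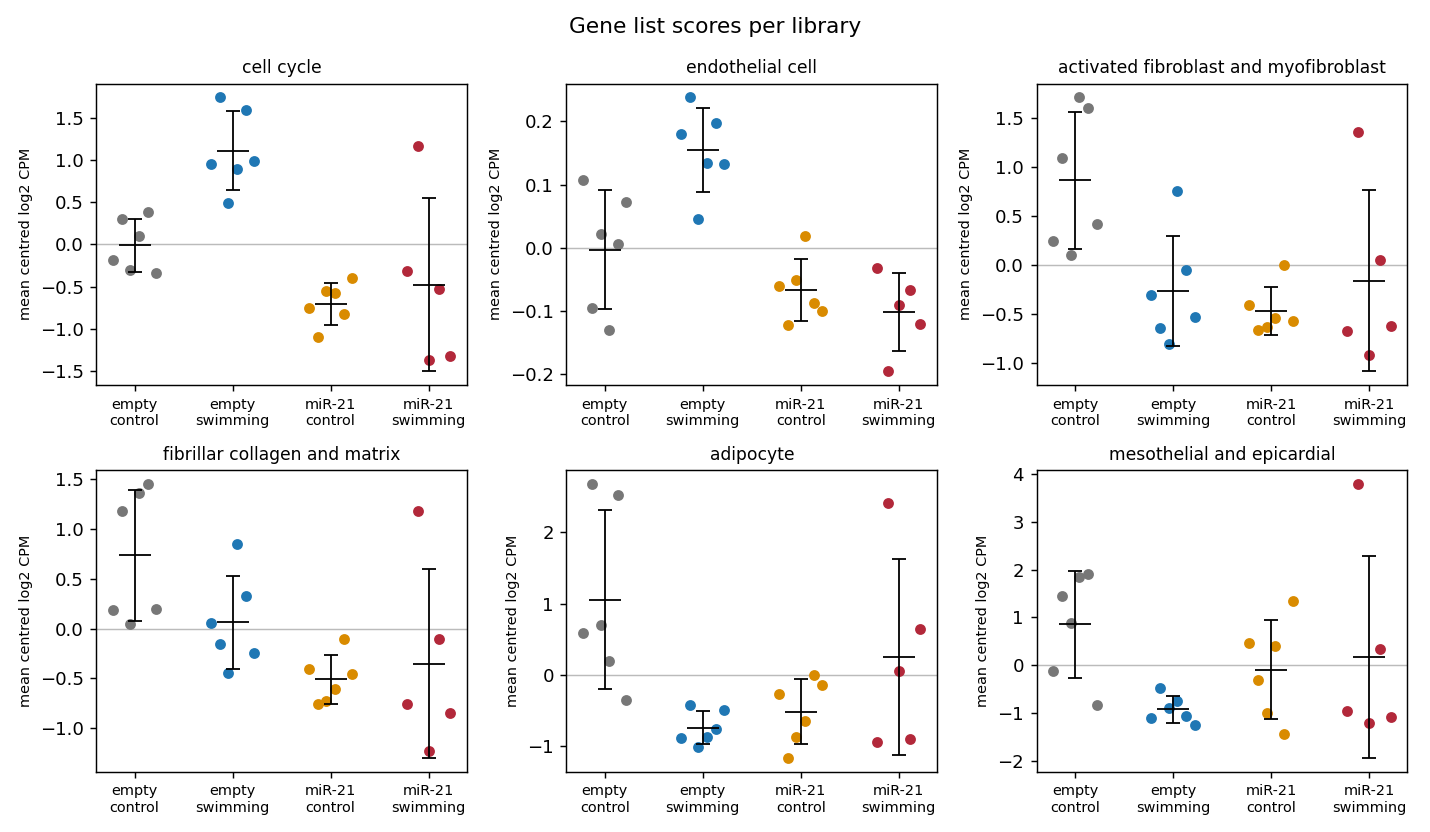
Scores of 6 gene lists (mean centred log2 CPM) in each library (points) of the 4 groups, with the mean and SD as bars. The adipocyte score exceeded 2.4 in 3 libraries and was at most 0.69 in the others.

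The miR-21 vector was compared with the empty vector in mice that did not swim, to ask what that vector changed without training. Genes of the scar matrix fell: Col11a1 by a log2 fold change of -3.64 ± 0.91 (SE, n = 6 and 6, adjusted p = 0.0436), Comp by -3.44 ± 0.85 (0.044), Cthrc1, a marker of activated fibroblasts, by -3.23 ± 0.84 (0.0486), P4ha3 by -2.80 ± 0.67 (0.0408) and elastin, Eln, by -1.79 ± 0.42 (0.0394). Acan (-3.58), Adamts4 (-2.74), Adam12 (-2.30), Apol6 (-3.16), Rgs1 (-3.02) and Cyp2e1 (-4.59) also fell. The largest rises were smaller: Tll2 1.21 ± 0.30 (0.0419), Plekhh1 1.10 ± 0.25 (0.0324), Chrna2 1.07 ± 0.24, the erythropoietin receptor Epor 0.93 ± 0.18 (0.0165) and the clock factor Hlf 0.89 ± 0.16 (0.0115). Each moved in its direction in 6 of 6 libraries of the miR-21 control group, against the mean of the empty vector controls. The naming rule required at least 5 for the largest rises and falls. Empty vector control replicates 2, 4 and 5 carry most of the Col11a1 and Comp falls. They had 5.08, 8.15 and 5.77 CPM of Col11a1 against at most 0.60 in the other controls. For Comp they had 168, 304 and 247 CPM against at most 57.2. Col11a1 in those others overlapped the miR-21 controls, which reached 0.51. Eln did not overlap, at 110 CPM or more in the empty vector controls and at most 68.7 in the miR-21 controls. Fat genes differed more without passing, such as Cfd (-5.72 ± 1.51, adjusted p = 0.0505), and rest on empty vector control replicates 2 and 5, with 148 and 114 CPM of Cfd. Of 23 libraries left out in turn, 9 kept the call of Col11a1, 9 of Comp, 8 of Cthrc1, 12 of P4ha3 and 13 of Eln, with values from -3.91 to -1.53 and the highest adjusted p (0.109 to 0.124) without empty vector control replicate 5. With the adipocyte and mesothelial scores as covariates all of these genes lost their call (edgeR adjusted p from 0.173 to 0.248). Without the 3 adipocyte-high libraries Comp, Cthrc1, P4ha3 and Eln kept it (0.0188 to 0.0496). Both alternatives were chosen after seeing the data.

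In the fibrillar collagen and matrix list 6 of 35 genes fell, 34 adjusted over the list alone, with a median of -1.13 (camera adjusted p = 4.71e-17, adjusted p = 0.497 with an estimated correlation). In the activated fibroblast list 5 of 29 fell, 25 adjusted over the list alone, with a median of -1.38 (camera adjusted p = 7.63e-13, adjusted p = 0.497 with an estimated correlation). The contractile genes Tagln (-0.99 ± 0.23), Cnn1 (-1.25 ± 0.29) and Mylk (-0.36 ± 0.08) and the vessel wall gene Mcam (-0.53 ± 0.10) fell. Fatty acid oxidation genes rose by a median of 0.35, with 1 of 29 changed, Cpt2 at 0.48 ± 0.13, and 24 adjusted over the list alone (camera adjusted p = 2.86e-10, adjusted p = 0.497 with an estimated correlation). Oxidative phosphorylation rose by a median of 0.27 with 0 of 39 genes changed by edgeR (camera adjusted p = 3.27e-10, adjusted p = 0.497 with an estimated correlation). In the clock list 6 genes rose and 2 fell, with Tef at 0.65 ± 0.10 (0.00431), Wee1 at 0.66 ± 0.13 and Arntl at -1.41 ± 0.30 (camera adjusted p = 0.0266, adjusted p = 0.497 with an estimated correlation). Bmp2 (-1.40 ± 0.28), Sfrp1 (-1.82 ± 0.39), Cdkn1a (-1.12 ± 0.22) and Rcan1 (-0.69 ± 0.15) fell. Exact permutation p was 0.00216, the smallest that the splits can give, for the matrix, activated fibroblast and fatty acid oxidation scores, 0.0123 adjusted over 34 lists.

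Further lists called downwards were macrophage (median -1.05), neutrophil (-2.81), T and NK cell (-0.93), mesothelial (-1.08), cardiac stress (-0.67), TGF-beta (-0.40), Wnt (-0.33), interferon (-0.32), inflammatory cytokines (-0.84), immediate early genes (-0.33), cell cycle (-0.79) and apoptosis and p53 (-0.23). Sarcomere (0.22) and ion channel (0.32) lists were called upwards. With an estimated correlation these 14 lists had adjusted p from 0.497 to 0.638. The camera direction turned with the tissue covariates for T and NK cell (mean 0.16) and mesothelial (-0.050). The mean differed in sign from the median for the atrial, nerve, skeletal muscle, SoxF, exercise-linked and oestrogen-linked lists, and the miR-21 targets had a median of -0.03 beside a camera direction of up, none of them called. With the adipocyte and mesothelial scores as covariates, an alternative chosen after seeing the data, 13 genes changed, and DESeq2 gave 1219. The count of 304 became 618, 145, 709, 25 and 17 without empty vector control replicates 1 to 5, 117, 147, 126 and 148 without empty vector swimming replicates 1, 2, 5 and 6, 43, 18, 49, 71, 73 and 91 without miR-21 control replicates 1 to 6, and 2885, 520 and 138 without miR-21 swimming replicates 2, 3 and 4.

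The miR-21 vector was compared with the empty vector in swimming mice, to ask what that vector changed after training. Endothelial genes fell: Rasip1 by a log2 fold change of -0.39 ± 0.07 (SE, n = 5 and 6, adjusted p = 0.00256), Icam2 by -0.66 ± 0.12 (0.00357), the cadherin Cdh5 by -0.46 ± 0.09 (0.00624), Esam by -0.41 ± 0.09 (0.00882), nitric oxide synthase Nos3 by -0.39 ± 0.09 (0.0115), the VEGF receptor Kdr by -0.39 ± 0.11 (0.039) and Sox7. Mitotic genes also fell, with Esco2, Fam64a, Prc1, Ckap2l, Pbk, Bub1, Aspm, Mxd3 and Troap between -2.98 and -2.30, and the cyclin Ccnd1 at -0.94 ± 0.12 (0.000258). Pydc3 fell by -4.03 ± 0.53 (0.000258), and Rab4a, a small GTPase of endosomes, rose by 1.75 ± 0.13 (3.59e-08). Rab4a averaged 4.56 CPM in the empty vector swimming group and 13.5, 16.3 and 15.4 in the others. In Pydc3, Rab4a, Rasip1, Icam2, Ccnd1, Fam64a, Pbk, Aspm and Mxd3 the empty vector swimming libraries lay outside the range of all 17 others. For these genes the comparison does not separate an effect of the vector from a trait of that group. The largest rises were the mesothelial Upk3b (7.43 ± 1.78, 0.0207) and the collagen gene Col6a5 (7.22 ± 1.94, 0.0372), followed by Plppr3 (2.24), Slc6a7 (2.19) and Wisp2 (2.02). Each moved in its direction in 5 of 5 libraries of the miR-21 swimming group, which the naming rule required of the largest rises and falls. Replicate 2 carries the size of the Upk3b and Col6a5 rises, with 55.8 and 49.2 CPM against at most 2.21 and 1.03 in the other 4. Without it Upk3b was 3.41 (adjusted p = 0.175) and Col6a5 2.44 (0.476).

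In the endothelial list 9 of 27 genes fell, 17 adjusted over the list alone, with a median of -0.24 (camera adjusted p = 9.33e-09, adjusted p = 0.156 with an estimated correlation). In the cell cycle list 7 of 26 fell, 22 adjusted over the list alone, with a median of -1.42, among them Aurka (-1.45 ± 0.35) and Cdc20 (-1.57 ± 0.38) (camera adjusted p = 2.27e-20, adjusted p = 0.275 with an estimated correlation). In the list of SoxF factors and their endothelial partners 3 of 13 fell, 6 adjusted over the list alone (camera adjusted p = 0.00644, adjusted p = 0.782 with an estimated correlation). The exact permutation p of the scores was 0.00216 for the endothelial, 0.0173 for the cell cycle and 0.00433 for the SoxF list, and 0.0491, 0.118 and 0.0491 adjusted over 34 lists. Col5a3 (-1.22 ± 0.23) and Col6a3 (-0.99 ± 0.24) fell in the matrix list, whose median was -0.24 (camera adjusted p = 0.000701, adjusted p = 0.828 with an estimated correlation). Mcam (-0.71 ± 0.10, 0.00056), Wif1 (-1.65 ± 0.34), Fhl1 (-0.74 ± 0.16) and the interferon gene Xaf1 (-0.35 ± 0.08) fell, and Cxcl14 (1.34 ± 0.32), Nrg1 (1.68 ± 0.48), Fgf12 (2.53 ± 0.58) and Ptgds (0.91 ± 0.21) rose.

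Interferon response (median -0.12) and oxidative phosphorylation (-0.14) were also called downwards, and neutrophil (3.47), B cell (2.21) and mesothelial lists (1.82, with 5 of 13 genes up) upwards, each with adjusted p = 0.828 with an estimated correlation. The activated fibroblast list had a median of 0.22 and a mean of 0.31 beside a camera direction of down, and was not called. Its mean turned to -0.36 without miR-21 swimming replicate 2, and to -0.47 with the tissue covariates. The mean of the oxidative phosphorylation list was -0.12 and became 0.02 without miR-21 swimming replicate 2, without which the mean of the mesothelial list went from 3.39 to 0.76 (camera adjusted p = 0.958), of the neutrophil list from 3.17 to 0.60 (0.308) and of the B cell list from 2.47 to 0.26 (0.677). Interferon response went from -0.12 to 0.0014 (0.285) without replicate 5, and the mesothelial list had a camera adjusted p of 0.0606 without replicate 4. The count of 618 became 330, 406 and 339 without empty vector swimming replicates 2, 4 and 5, and 404, 1871 and 362 without miR-21 swimming replicates 1, 2 and 5.

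Swimming with the miR-21 vector was compared with no swimming, to ask whether training acted in mice given that vector. Of the 23 changed genes, 7 rose, among them Maml3, a coactivator of Notch, by a log2 fold change of 0.64 ± 0.13 (SE, n = 5 and 6, adjusted p = 0.0407), Miip by 0.40, Cdc42bpg by 0.36, Tcof1 by 0.31 ± 0.05 (0.0345), Golgb1 by 0.28 and the survival gene Mcl1 by 0.27 ± 0.05 (0.0407). Hpdl fell by -1.03 ± 0.19 (0.0407), the crystallin Cryba4 by -0.86 ± 0.18 (0.0476), the selenoprotein Msrb1 by -0.57 ± 0.10 (0.0345), and Rnmtl1, Tmem258, Ciapin1 and Tmem150a by -0.61 to -0.42. The ribosomal protein genes Rps29 (-0.57 ± 0.11), Rps13 (-0.41 ± 0.09) and Rplp2 (-0.39 ± 0.07) fell. Each moved in its direction in 5 of 5 libraries, which the naming rule required of the largest rises and falls.

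Fatty acid oxidation (median -0.24, camera adjusted p = 4.16e-09) and oxidative phosphorylation (-0.23, 2.08e-10) were called downwards with 0 genes changed by edgeR in either, each with adjusted p = 0.85 with an estimated correlation. The sarcomere list (-0.17) was called downwards and the interferon (0.30) and neutrophil (4.40) lists upwards, each with adjusted p = 0.85 with an estimated correlation. Without miR-21 swimming replicate 2, whose neutrophil score was 4.65 against at most 0.75 in the other 4, the mean of the neutrophil list went from 3.43 to 0.85 (camera adjusted p = 0.182), of the interferon list from 0.34 to 0.12 (0.0971) and of the sarcomere list from -0.17 to -0.052 (0.298). The exact permutation p of the fatty acid oxidation score was 0.0455 over 462 splits, and 0.515 adjusted over 34 lists. With a term for the title number series 1076 genes changed, and DESeq2 gave 395, voom 314 and edgeR on these 2 groups alone 0. With that term the effect is set by miR-21 swimming replicates 1 and 2, the libraries of the same series as the controls. The count of 23 became 58 and 13 without empty vector control replicates 2 and 6, 9 and 2 without empty vector swimming replicates 2 and 5, 0, 1, 0, 0 and 0 without miR-21 control replicates 1, 2, 3, 4 and 6, and 1, 13, 8, 9 and 86 without miR-21 swimming replicates 1 to 5.

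The interaction asks in which genes the effect of swimming differed between the vectors. Of 73 genes, 44 had a more positive effect with miR-21. Fat genes led these: Cfd by a log2 difference of 11.13 ± 2.17 (SE, n = 6, 6, 6 and 5, adjusted p = 0.0291), Car3 by 9.78 ± 1.97 (0.0291), Cidec by 9.62 ± 2.16 (0.0455) and Adipoq by 9.49 ± 1.90 (0.0291). These sizes rest on 3 libraries, with 148 and 114 CPM of Cfd in empty vector control replicates 2 and 5 and 147 in miR-21 swimming replicate 2, against at most 8.47 in the other 20. Without the 3, Cfd was 4.17 (adjusted p = 0.0698), Car3 3.49 (0.121) and Adipoq 3.36 (0.0982), and 53 genes changed, 24 up and 29 down, of which 24 were among the 73. With the tissue covariates Cfd was 0.84 (0.401) and Cidec -1.03 (0.749). Comp (6.28 ± 1.22, 0.0291), the proline transporter Slc6a7 (4.90 ± 0.77, 0.00375), Wisp2 (3.75 ± 0.79, 0.033), Cxcl14 (2.10 ± 0.43), Bmp2 (2.05 ± 0.41) and Inhbb (1.37 ± 0.32) followed, with Cyp2e1, Chil1, Apol6 and Anxa8 between 4.69 and 8.15. Comp was 186 CPM in miR-21 swimming replicate 2 against at most 45.9 in the rest of that group. It was 168, 304 and 247 CPM in empty vector control replicates 2, 4 and 5 against at most 57.2 in the others. Wisp2 also varied widely in the miR-21 swimming group, at 45.5 ± 50.2 CPM (SD). A more negative effect with miR-21 was called for Wif1 (-2.37 ± 0.48, 0.0291), the imprinted gene Mest (-1.86 ± 0.42, 0.0444), Mlf1 (-1.08), Tspan2 (-0.99 ± 0.18, 0.0135), Cyp4b1 (-0.99 ± 0.17, 0.00812), Fbxl22 (-0.96), Akr1c14 (-0.88 ± 0.16, 0.0118), the kinase Wee1 (-0.86 ± 0.18, 0.0291), Dach1 (-0.81) and Car8 (-0.77).

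The activated fibroblast list had a more positive effect of swimming with miR-21, by a median of 1.25, with 2 of 29 genes changed and 13 adjusted over the list alone (camera adjusted p = 2.39e-08, adjusted p = 0.528 with an estimated correlation). Its mean went from 1.84 to 1.16 without miR-21 swimming replicate 2, 0.92 without the 3 adipocyte-high libraries and 0.49 with the tissue covariates (camera adjusted p = 0.152). Fatty acid oxidation (median -0.38, camera adjusted p = 1.65e-09) and oxidative phosphorylation (-0.39, 3.91e-13) had a more negative effect, each with adjusted p = 0.528 with an estimated correlation. With the tissue covariates the direction of oxidative phosphorylation turned (mean 0.018). In all 19 lists were called, 12 more positive and 7 more negative, with 0 passing on an estimated correlation. DESeq2 gave 754 genes and the title number series 25. The count of 73 became 147, 38, 19 and 174 without empty vector control replicates 3 to 6, 25, 38, 45, 18 and 27 without empty vector swimming replicates 1, 2, 3, 5 and 6, 34, 25, 21 and 26 without miR-21 control replicates 1 to 4, and 243, 32, 305 and 358 without miR-21 swimming replicates 1, 2, 3 and 5.

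Gene Ontology terms called by camera numbered 19 up and 31 down of 2059 for swimming with the empty vector, 67 and 206 for the miR-21 vector without swimming, 6 and 42 with swimming, 8 and 74 for swimming with the miR-21 vector, and 81 and 44 for the interaction. With an estimated correlation 0 terms passed in any comparison. Extracellular matrix led without swimming (173 genes, median -0.61, adjusted p = 1.47e-10, adjusted p = 0.638 with an estimated correlation). The structural constituents of the ribosome led for the miR-21 vector with swimming, with 24 of 147 genes down and a median of -0.17 (adjusted p = 1.04e-15, adjusted p = 0.988 with an estimated correlation). The respiratory chain led for swimming with the miR-21 vector (47 genes, median -0.26, adjusted p = 1.97e-16, adjusted p = 0.868 with an estimated correlation) and for the interaction (median -0.43, adjusted p = 2.25e-18, adjusted p = 0.793 with an estimated correlation). In KEGG, DNA replication rose with swimming under the empty vector, with 6 of 35 genes up (adjusted p = 6.76e-06, adjusted p = 0.675 with an estimated correlation).

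A miR-21 that acts through its seed would lower messages with a matching site in the 3' UTR. Of 13290 genes searched, 1093 had the 7-base site of miR-21-5p, ATAAGCT. Genes with the site differed from those without by a mean log2 fold change of 0.05 for the miR-21 vector without swimming (two-sided p = 0.197 by rank among other words, n = 1408) and -0.00 with swimming (0.757). The other differences were 0.03 for swimming with the empty vector (0.543), -0.02 for swimming with the miR-21 vector (0.675) and -0.05 for the interaction (0.54). For miR-21-3p the p for the miR-21 vector was 0.584 without swimming and 0.866 with it. In simulated fold changes drawn independently for each gene, a difference of -0.10 planted in the genes with the miR-21-5p site was recovered as -0.101. Its p was the smallest the words can give, 0.00071. Smaller differences were not tried, nor was one planted in the measured fold changes, so how small an effect the test can find is not known. Of 27 tested genes from a list of published miR-21 targets 20 had the site, and the list was not called in any comparison. The 3' UTR of Sox7 has 2073 bases, 0 full 7-base sites of miR-21-5p, 1 site that matches its shorter seed followed by A, and 1 site of miR-21-3p.

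**Figure D4:**
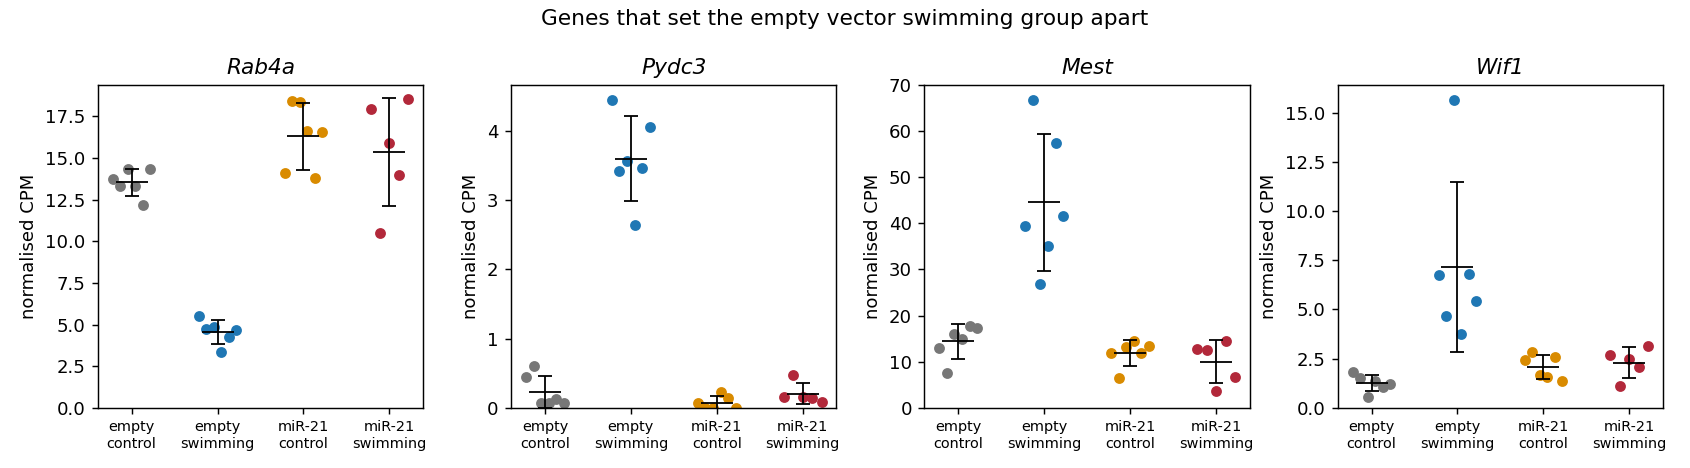
Normalised CPM of Rab4a, Pydc3, Mest and Wif1, genes chosen after their values were seen, in each library (points) of the 4 groups, with the mean and SD as bars; the axes start at 0. In each panel the 6 empty vector swimming libraries lie outside the range of the other 17.

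Both effects of the vector and both effects of swimming can be set side by side without a shared library. Across genes, which are not independent replicates, the log2 fold changes of swimming with the empty and with the miR-21 vector had a Pearson r of -0.45 and a Spearman rho of -0.12. Of the 1007 genes changed with the empty vector, 620 (61.6%) moved the same way with the miR-21 vector, by a median of 0.05 against 0.51. The miR-21 vector without and with swimming had r = -0.36 and a Spearman rho of -0.033 across genes, and 207 of 304 genes (68.1%) moved the same way. In both comparisons 27 genes were called, 23 of them in the same direction. The adipocyte-high libraries, empty vector control replicates 2 and 5 and miR-21 swimming replicate 2, enter each of these pairs of comparisons with opposite sign. Their tissue can make r negative, and r was not computed without them. Neither r thus shows that miR-21 reverses an effect of swimming, or swimming one of the vector.

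Comparisons that share a group correlate by construction. Swimming with the empty vector and the miR-21 vector with swimming, which share the empty vector swimming group with opposite sign, had r = -0.81 across genes against a mean of -0.48 in 20 simulations of unchanged groups, and a covariance of -0.211 against -0.0276. Of the genes called in both, 159 rose in the first and fell in the second and 86 did the reverse, where independent calls would give 15.3 and 8.27. With the shared group split into separate sets of libraries, r averaged -0.71 and those numbers 29.95 and 9.75, where independent calls would give 1.69 and 0.366. The simulations draw each gene independently, so they hold no tissue content that many genes of a library share. The adipocyte-high libraries lie in the groups not shared here, and a split of the shared group does not remove them. The excess over simulation is thus not shown to be an effect of swimming or miR-21. Swimming and the miR-21 vector, each against the empty vector control, had r = 0.65 (0.49 simulated), a covariance of 0.157 (0.0269 simulated), and 41 genes up and 43 down in both, where independent calls would give 4.97 and 6.07. With the shared control split, r averaged 0.43 and the numbers 3.45 and 3.05, where independent calls would give 1.36 and 2.49. Over the 20 splits the number down in both ran from 0 to 14, and the number from independent calls from 0 to 28.8. Single splits thus weigh heavily on these averages, and whether the number down in both exceeds chance stays open.

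Log2 fold changes in the authors' tables and here had Pearson r of 0.9996 or more across 13501 genes. The authors' tables hold 686 genes with q under 0.05 for swimming with the empty vector, 1088 for the miR-21 vector without swimming, 144 with swimming and 22 for swimming with the miR-21 vector, and 533, 239, 136 and 4 of these were called here. Their Sox7 value for the miR-21 vector with swimming is -0.84 (q = 0.01), and for swimming with the empty vector 0.56 (q = 0.0702).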

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

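Of the tests in this part, those of a swimming effect under either vector, of a batch shared by the title numbers and of the share of other cells were chosen only after the result was seen.

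Of 204 groups of values searched for a library far from the rest of its group, 25 had one, where chance alone flags about 1 in 20. Replicate 2 of the miR-21 swimming group was that library in 15 of the 25. Its list scores were 4.65 for neutrophils, 3.70 for B cells, 0.87 for Wnt, 0.80 for nerve and 0.19 for the miR-21 targets, and -0.80 for oxidative phosphorylation, -0.65 for ion channels, -0.61 for the sarcomere and -0.22 for SoxF partners. Its genes were Upk3b at 55.8 CPM, Col6a5 at 49.2, Cyp2e1 at 23.8, Cidec at 15.2, Esco2 at 0.882 and Pydc3 at 0.471. Replicate 4 of the empty vector swimming group stood out for cardiac stress genes (0.51), Upk3b (0.209 CPM), Col11a1 (1.53 CPM) and Col6a5 (0.278 CPM), and replicate 3 for Wif1 (15.7 CPM). The others were the pericyte score of miR-21 swimming replicate 1 (0.14), the SoxF score of miR-21 control replicate 2 (-0.19), the interferon score (0.067) and Col6a5 (6.32 CPM) of miR-21 control replicate 6, and Vmp1 in empty vector control replicate 2 (88.3 CPM).

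The effect of swimming differed between the vectors in 73 genes. The log2 difference, miR-21 minus empty, was 11.13 for Cfd, 9.78 for Car3, 9.62 for Cidec, 9.49 for Adipoq, 8.15 for Cyp2e1, 8.03 for Chil1, 6.28 for Comp, 4.90 for Slc6a7, 4.84 for Apol6 and 4.69 for Anxa8. It was -2.37 for Wif1, -1.86 for Mest, -1.08 for Mlf1, -0.99 for Tspan2, -0.99 for Cyp4b1, -0.96 for Fbxl22, -0.88 for Akr1c14, -0.86 for Wee1, -0.81 for Dach1 and -0.77 for Car8. The mean difference of the 19 lists called by camera was 5.72 for neutrophil, 4.37 for mesothelial, 3.62 for B cell, 1.84 for activated fibroblast, 1.80 for macrophage, 1.56 for T and NK cell, 1.26 for inflammatory cytokines, 1.22 for matrix, 1.02 for cardiac stress, 0.99 for Wnt, 0.66 for immediate early genes and 0.58 for TGF-beta. It was -0.52 for cell cycle, -0.43 for fatty acid oxidation, -0.39 for oxidative phosphorylation, -0.30 for ion channels, -0.23 for sarcomere, -0.21 for SoxF partners and -0.19 for endothelial genes. With an estimated correlation 0 of these lists passed, at adjusted p of 0.528 or more. Of the 19, 10 were also called without the 3 adipocyte-high libraries, where macrophage was 0.038, and 4 with the tissue covariates, in either direction. The covariates gave B cell -0.61, inflammatory cytokines -0.59, T and NK cell -0.56, macrophage -0.51, matrix -0.18 and mesothelial 0.31.

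In 70 genes the 6 empty vector swimming libraries lay outside the range of all 17 others, 51 higher and 19 lower, where chance would give 0.254 of 12809 genes. The other groups had 19, 10 and 17 such genes. To test causes, genes were chosen without the miR-21 swimming libraries: in 206 genes the 6 lay outside the 12 libraries without swimming, with a median step of 0.65. A batch that follows the title numbers would part replicates 3 to 5 from 1 and 2 of the miR-21 swimming group in these genes by about that step. Their signed median difference was -0.086 (quartiles -0.48 and 0.083), and -0.069 with replicate 1 alone as the lower series, which argues against such a batch behind most of them. Training that acts alike under either vector was tested on 596 genes chosen within the empty vector libraries alone, where swimming and control did not overlap (median step 0.49). In the miR-21 arm, which shares no library with these, their signed median was 0.053 (quartiles -0.069 and 0.20), and 361 of 596 moved the same way. As measured, most of them thus did not show a like step. The adipocyte-high libraries enter the 2 arms with opposite sign, however, which can pull this median towards 0. It was not computed without them, and choosing genes without overlap enlarges the step of 0.49. The test thus cannot decide whether training acts alike under either vector. A genetic difference of the mice in this group stays open: 14 of the 70 genes have another of them within 10 tested genes, such as Cav1 and Cav2, against a median of 6 in 1000 random sets, of which 35 had as many. The random sets were not matched for neighbours that are regulated together, so the excess does not single out inheritance. These values may reflect an inherited difference, but a batch of that group alone, or training that needs the empty vector, was not tested and cannot be separated from the group.

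The activated fibroblast list was lower than in the empty vector control by a mean of -1.21 with swimming and -1.54 with miR-21. For the first, the covariates left -0.36. By the prediction written before this result, under 50% of the size left would go with adipose and mesothelial tissue as the source. Leaving out the 3 adipocyte-high libraries, a condition that was not part of that prediction, left -0.96. With both in view, such tissue in some libraries cannot be told apart from swimming. For the miR-21 vector the covariates left -0.95, more than 50% of -1.54, and leaving out the 3 libraries left -1.28. This argues against fat and mesothelial content, as scored, as the whole cause, though no error was computed for these means. It does not cover other tissue differences: empty vector control replicate 4 had 304 CPM of Comp with 4.11 of Cfd. A smaller share of all cells other than cardiomyocytes would lower endothelial and fibroblast scores alike, but with swimming the endothelial score rose by 0.16 (exact permutation p = 0.0108). The macrophage, neutrophil, T and NK cell, B cell, adipocyte and mesothelial lists were called downwards with the fibroblast list. The endothelial rise thus speaks to all other cells together, and not to a smaller share of some of them. A direct effect of swimming or of miR-21 on fibroblasts stays open and untested.

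Of 82 ribosomal protein genes, 81 were lower and 23 changed with the miR-21 vector and swimming, at a median of -0.22 relative to all genes. After regression on length, GC content and level the median was -0.15, below the lowest of 1000 random sets (-0.0889). For swimming with the miR-21 vector the same regression turned the median from -0.074 to 0.099, above the highest random set (0.058). For the interaction it turned from -0.119 to 0.105 (highest random set 0.018). The regression thus moves these genes in either direction, and the random sets hold unrelated genes, so it cannot decide whether length, GC content and level are the cause. With 1 library of the miR-21 swimming group left out, the median relative to all genes for the miR-21 vector with swimming was -0.20 at the value nearest 0 (replicate 1, with 5 genes changed). It was -0.28 with 52 changed without replicate 2, so no single library of that group carries the fall. Without swimming 73 of the 82 genes were also lower with the miR-21 vector, at a median of -0.11 and of -0.26 after the same regression (lowest random set -0.032). There edgeR called 0 of them, with 16 at an unadjusted p under 0.05 and 1 by DESeq2, so whether the pattern is particular to trained mice stays open, as does an effect of miR-21.

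Of 100 splits of the libraries, only the real one, 1, gave as many changed genes in every comparison. For the comparisons of groups, this argues against a chance assignment of labels behind each count, at the smallest share that 100 splits can show. It does not make a count stable: the 23 genes for swimming with the miR-21 vector became 0 with no filter and 0 with 2 groups only. The real value and the highest of the other splits were 1007 and 84 for swimming with the empty vector, 304 and 2 for the miR-21 vector without swimming, 618 and 224 with swimming, 23 and 3 for swimming with the miR-21 vector, and 73 and 0 for the interaction. For the interaction the splits reshuffled swimming and control within each vector, which also removes any swimming effect common to both. The 73 and 0 thus do not test whether the effects of swimming differ between the vectors.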

How the results depend on the processing

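Leaving out the 3 libraries with the highest adipocyte scores, and the adipocyte and mesothelial scores as covariates, were alternatives chosen after the data were seen. The covariates are themselves means of listed genes, so they remove changes of those genes by construction. The title series term is set by miR-21 swimming replicates 3 to 5 against 1 and 2. Replicate 2 is adipocyte-high, so results with this term depend on its tissue and cannot be read as the removal of a batch. Where no reason is given, the cause was not tested.

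The count for swimming with the empty vector was within 1.5 times of 1007 with RLE or upper quartile scaling, either filter, DESeq2 and 2 groups only. It was 164 with a term for the title number series, 1716 with voom, 434 with the fold minimum, which removes genes by construction, 1555 without the 3 adipocyte-high libraries and 2144 with the tissue covariates. Without any 1 library it ran from 607 to 1922. For the miR-21 vector without swimming, 304 became 150 with no filter, where more genes are tested, 911 with the title series, 1219 with DESeq2, 1.4e+03 with voom (609 up and 744 down), 142 with the fold minimum, 1622 with 2 groups only, 771 without the 3 libraries and 13 with the covariates. Each library left out in turn gave 17 to 2885. For the miR-21 vector with swimming, 618 became 960 with DESeq2, 2715 with voom, 223 with the fold minimum, 165 with 2 groups only, 2318 without the 3 libraries and 2319 with the covariates. The range without 1 library was 330 to 1871. For swimming with the miR-21 vector, 23 became 41 with upper quartile scaling, 0 with no filter, 1076 with the title series, 395 with DESeq2, 314 with voom, 4 with the fold minimum, 0 with 2 groups only, 134 without the 3 libraries and 96 with the covariates. The same range here was 0 to 86, and edgeR with all libraries had 2532 genes at an unadjusted p under 0.05. For the interaction, 73 became 25 with the title series, 754 with DESeq2, 147 with voom and 44 with the covariates. With 1 library left out it was 18 to 358.

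Lists called numbered 21, 19, 9, 5 and 19 in the order of the report, and 0 in each with an estimated correlation. With the title series they were 11 for swimming with the empty vector, 4 for the miR-21 vector with swimming and 15 for swimming with the miR-21 vector. Without the 3 libraries they were 13 for swimming with the empty vector and 12 for the interaction. With the covariates they were 9 for swimming with the empty vector, 9 for the miR-21 vector without swimming and 6 for the interaction. Leaving out 1 library gave 6 to 14 for the miR-21 vector with swimming and 5 to 11 for swimming with the miR-21 vector, and counts within 1.5 times for the others. RLE scaling kept 33 or more of the 34 lists in each comparison, and the site tests of miR-21 did not pass under any alternative.

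The direction of the camera test turned for the lists below, given with their mean log2 fold change. For swimming with the empty vector, the title series gave sarcomere -0.20, matrix 0.44, macrophage 0.55, neutrophil 1.10, B cell 1.57, mesothelial 0.79, fatty acid oxidation -0.30, oxidative phosphorylation -0.20, Wnt 0.16, inflammatory cytokines 0.042 and ion channels -0.10. The covariates gave sarcomere -0.25, matrix 0.14, macrophage 0.49, neutrophil 1.11, T and NK cell 0.45, B cell 0.75, mesothelial -0.50, fatty acid oxidation -0.14, oxidative phosphorylation -0.18, inflammatory cytokines 0.28 and ion channels -0.083. They also turned Cidec (0.27), Car3 (0.057) and Cyp2e1 (0.11). For the miR-21 vector without swimming, the covariates gave T and NK cell 0.16, B cell 0.61 and mesothelial -0.050. For the miR-21 vector with swimming, they gave sarcomere 0.14, macrophage -0.65, B cell 0.00082, mesothelial 0.26, oxidative phosphorylation 0.049 and inflammatory cytokines -0.64. Without the 3 libraries macrophage was -0.31, fatty acid oxidation 0.091 and oxidative phosphorylation 0.019, and the title series gave oxidative phosphorylation 0.013. For swimming with the miR-21 vector, matrix was -0.21 without the 3 libraries. For the interaction, the covariates gave sarcomere 0.14, matrix -0.18, macrophage -0.51, T and NK cell -0.56, B cell -0.61, mesothelial 0.31, oxidative phosphorylation 0.018, interferon -0.27, inflammatory cytokines -0.59, ion channels -0.060 and Cidec -1.03. Without the 3 libraries sarcomere was 0.0074, macrophage 0.038 and interferon -0.16.

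Without miR-21 swimming replicate 2, 4 list tests turned. Over all libraries left out, the mean ran from -0.36 to 0.85 for macrophage, 0.76 to 3.65 for mesothelial and -0.18 to 0.024 for oxidative phosphorylation with the miR-21 vector and swimming, and from -0.18 to 0.64 for matrix with swimming and the miR-21 vector.

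Of simulated 1.5-fold changes edgeR recovered 38.8% in the interaction (13426 genes) and 55.2% to 62.7% in the other comparisons. Depth was not varied, so what it limits is not known.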

Other observations

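Of the circadian clock list, Hlf, Tef and Wee1 rose with swimming under the empty vector by log2 fold changes of 0.70 ± 0.16, 0.43 ± 0.10 and 0.94 ± 0.13 (SE, edgeR adjusted p = 0.0107, 0.0132 and 0.00012), and with miR-21 without swimming by 0.89 ± 0.16, 0.65 ± 0.10 and 0.66 ± 0.13 (adjusted p = 0.0115, 0.00431 and 0.0164). The list as a whole was not called for swimming with the empty vector, and for miR-21 its camera adjusted p was 0.0266, or adjusted p = 0.497 with an estimated correlation. Both comparisons use the same 6 control libraries. The hours at which hearts were taken are not in the labels.

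Rab4a, chosen after its values were seen, averaged 4.56 CPM in the empty vector swimming group and 13.5, 16.3 and 15.4 in the empty vector control, miR-21 control and miR-21 swimming groups. The unnamed gene model Gm41885, also chosen after its values were seen, averaged 0.0735 CPM there and 12.8, 7.51 and 8.19 elsewhere.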
